A study of Mus musculus with 12 samples.

How the data were processed

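RNA-seq was done on microglia enriched by magnetic sorting from the brains of adult mice that had received a bone marrow transplant, either with the head shielded from the irradiation or without a shield. Per the labels' protocols, RNA was linearly amplified before library preparation, so differences in amplification between samples are part of the spread between libraries. Per the submitters' processing notes, FastQC, STAR and HTSeq were used with the mouse genome build mm9; the versions, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited table holds whole-number read counts per gene, per the file headers and values, for 36491 Ensembl gene identifiers in 12 libraries. Every row had at least 2 counts over all libraries, so genes without reads are not listed. All columns were matched to samples by name.

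Symbols were taken from the reference table of gene names; 254 identifiers had none and 6 shared a symbol with another, and these kept their identifiers. The reference annotation is on another build than mm9, so it was used only to see which genes overlap and for GC content and transcript length, and no coordinates are given. With the strand setting unknown, genes that share exons with a neighbour are uncertain. Among those named in the text under the rule given below these are Ch25h, Csf1r, Fdps, Gpr65, H2-Oa, Hmgcs1, Ifitm2, Jaml, Klk8, Ldhd, Ms4a6c, Pilra, Plpp1, Pltp, Sox4 and Spp1. Genes named only as part of the iron and metal set were not checked for shared exons. Members of families with similar copies (Ifi204 and Ifi205, Slfn, Ms4a, Klra2, the H2 genes, Bcl2a1a, Ccl12, Fpr1 and Fpr2) are uncertain because a read can match more than 1 copy.

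Samples were grouped by their titles into 4 groups of 3. For 2 of the shielded libraries titled as not given LPS, numbers 2 and 3, the treatment field says LPS. The groups follow the titles, and both other readings (leaving these libraries out, or grouping them by the field) were run as alternatives. Nothing in the labels says whether the samples of a group are separate animals, so p-values measure the spread between these samples, which may be technical. Within a group the libraries were not copies of one another, since the chi-square per degree of freedom between any pair was at least 13.

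Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust dispersion, TMM scaling, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) in one model over all 12 libraries. The filterByExpr function (minimum count 10, minimum total 15) left 18875 genes. All adjusted p-values of genes below come from this test unless another tool is named. Standard errors (SE) of log2 fold changes are the absolute log2 fold change divided by the square root of the test's F statistic. They were not estimated directly by the fit. Values per library are CPM computed from the deposited counts with TMM scaling, and log2 CPM used a prior count of 2. A total of 27 gene lists was fixed before the data were examined and tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The marrow-derived macrophage, microglia and disease-associated lists came from general knowledge of published work, which may include work on these samples, so their directions are not independent evidence.

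The genes named in the text, apart from some of the iron and metal set examined afterwards, were chosen by a rule fixed before the data were examined. For each comparison it takes the 10 genes with the largest fold change in each direction among those past the threshold with a mean log2 CPM of at least 3 and, except for the difference of LPS effects, no overlap between the groups' values, leaving out predicted and unnamed genes. It adds, for each list, the called members with the smallest p in each direction and a fixed set of LPS-response, microglia and macrophage genes. Some were left out of the text for length, and some are not reported here.

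On simulated counts drawn from the real means and library sizes, with 200 genes changed, the test recovered 62% of 2-fold and 98% of 4-fold changes for the LPS effect in shielded mice, 75% and 91% in unshielded mice, 75% and 94% for the shield without LPS, and 82% and 96% for the shield after LPS. It made 10 to 14 false calls in each comparison, beside the 200 changed genes, among 18875 genes. The simulated genes varied independently, and the real comparisons by LPS or shield called 10.8 to 67.5% of genes. These rates therefore need not hold for the real calls. Library totals ran from 18090977 to 60495968 counts, and the unshielded LPS libraries were the deepest.

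The replicate numbers come from the titles. Deviations from the group means of shielded libraries with the same number correlated at 0.112, 0.194 and 0.547 across genes between the LPS and no-LPS groups. These 6 libraries met the rule set for this work, a correlation over 0.1 in every same-numbered pair. The rule makes no comparison with pairs of different numbers. Shielded LPS library 1 correlated at 0.399 with shielded library 2 without LPS, and the other such pairs at -0.483 to -0.014. Meeting the rule therefore cannot show that the numbers pair the libraries, and nothing in the labels says what a number stands for. No other comparison met the rule. Alternatives tried were DESeq2 1.42.0, limma-voom, other scalings, other low-count filters, a 2-fold minimum, the replicate number as a block, each library left out in turn and both other readings of the conflicting labels. A covariate for neuron and oligodendrocyte RNA, and a fit of the shielded groups alone with the block, were added after seeing the data.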

Results

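Gene expression was measured by RNA-seq in microglia sorted from the brains of mice that had received bone marrow transplants. Head shielding during irradiation keeps the brain out of the field, whereas unshielded mice have the whole body irradiated. All mice then ate food containing PLX5622, an inhibitor of the CSF1 receptor that depletes microglia, for 2 weeks, followed by standard chow for 6 weeks. They were injected intraperitoneally with 50 µg of lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor 4, or with saline, and cells were collected 6 hours later. Each of the 4 groups had 3 libraries. Library totals ran from 29794946 to 40730784 counts in shielded LPS mice, 28770354 to 42931839 in shielded mice without LPS, 56776710 to 60495968 in unshielded LPS mice and 18090977 to 40792878 in unshielded mice without LPS. The series asks how macrophages from outside the brain, which can take the place of depleted microglia, respond to a peripheral immune challenge.

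Because the labels of 2 shielded libraries conflict, 10 LPS-response genes (Il1b, Tnf, Cxcl10, Ccl5, Isg15, Il1rn, Saa3, Lcn2, Acod1 and Gbp2) were read in every library first. Their mean log2 CPM was 8.66, 8.10 and 8.20 in the shielded LPS libraries and 7.34, 7.89 and 7.70 in the unshielded LPS libraries. The libraries labelled as shielded without LPS stood at 3.75, 3.31 and 2.94, of which the second and the third carry the conflicting field. Those labelled as unshielded without LPS stood at 3.15, 3.17 and 4.51. The lowest LPS library lay 2.83 above the highest library without LPS, and both libraries with conflicting fields sat with the libraries without LPS. That argues against the treatment field of these 2 libraries. Grouping them by the field joins libraries with and without this response. Unshielded library 3 without LPS stood above its companions in this mean. It had 29.5 CPM of Saa3 against 0.707 and 1.11, and 44.4 CPM of Lcn2 against 5.50 and 7.27. Its Il1b (136.8 CPM against 222.6 and 179.9) and Tnf (35.59 against 52.15 and 43.82) lay below both companions. Its Cxcl10 lay between them (24.93 CPM against 28.44 and 19.6).

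**Figure D1:**
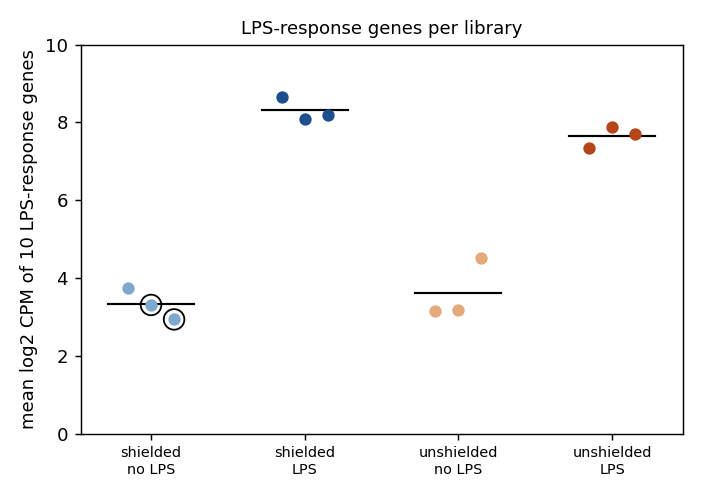
Mean log2 CPM of the 10 LPS-response genes (vertical axis) in each of the 12 libraries, by group. Points are libraries in replicate order, lines are group means, and circles mark the 2 libraries whose title and treatment field conflict; all LPS libraries lie at or above 7.34 and all others at or below 4.51.

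The first comparison asked what LPS did to cells from shielded mice. Inflammatory and antimicrobial genes rose most. Saa3, an acute-phase serum amyloid (ENSMUSG00000040026), went from 0.726 ± 0.566 to 794.1 ± 117.6 CPM (SD, n = 3 each), a log2 fold change of 10.03 ± 1.36 (SE; edgeR adjusted p = 8.04e-05). The chemokine Ccl5 rose by 6.60 ± 0.55, Acod1, which makes itaconate, by 6.53 ± 0.56, the interferon-inducible Ifi205 by 6.50 ± 0.51 and the interleukin-1 receptor antagonist Il1rn by 6.37 ± 0.44. Il12b, a subunit of interleukins 12 and 23, rose by 6.13 ± 0.61, the kinase gene Ikbke by 6.02 ± 0.36, Lipg by 5.76 ± 0.51, Steap4 by 5.71 ± 0.55 and the B-cell attractant Cxcl13 by 5.71 ± 0.62. The largest decreases were in Cmah (-5.24 ± 0.45), Gdf3 (-4.75 ± 0.76), the transporter gene Slco1a4 (-4.58 ± 0.37), Cbfa2t3 (-4.12 ± 0.26) and Tspan18 (-4.02 ± 0.36). EdgeR adjusted p-values of these genes were at most 0.000262. Without shielded LPS library 3 the log2 fold change of Gdf3 was -7.71 and that of Cmah -5.84. Without shielded LPS library 1 Il12b was 5.41, Cxcl13 5.07 and Gdf3 -4.11, and without shielded library 1 without LPS Saa3 was 10.95, Il12b 6.77 and Gdf3 -4.13. Without the libraries with conflicting fields Saa3 was 9.17, Il12b 5.42, Lipg 5.16 and Gdf3 -5.49.

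By group, all 30 interferon-response genes, all 24 NF-kB targets, all 15 acute-phase and antimicrobial genes and 22 of 23 cytokines and chemokines rose, with median log2 fold changes of 2.21, 2.34, 4.22 and 2.59. Examples were Ifit1 (3.24 ± 0.20), Isg15 (3.76 ± 0.30), Marcksl1 (3.51 ± 0.18), Fpr1 (5.13 ± 0.30) and Ccl12 (3.94 ± 0.25). Of the LPS receptor and adaptor genes 13 of 15 rose, among them Irak3, a brake on Toll-like receptor signalling (2.90 ± 0.14), and Cd14 (2.61 ± 0.19), whereas Ly96 (-0.66 ± 0.14) and Tlr4 (-0.30 ± 0.09) fell. The Tlr4 call was lost without shielded LPS library 2 (edgeR adjusted p = 0.0735), without shielded library 2 without LPS (adjusted p = 0.0589) and with the replicate number as a block in the shielded groups alone (adjusted p = 0.0502). MHC class I (11 of 13), complement (11 of 13), glycolysis (12 of 15, led by Ldha, 2.48 ± 0.12) and cholesterol synthesis (11 of 16) also had mostly rising members, and 2 fell in each of the last 2 lists. Of 29 microglia identity genes 17 fell and 1 rose. P2ry12, a purine receptor (-1.98 ± 0.19), Sall1, a transcription factor of microglia (-1.45 ± 0.39), and Gpr34 (-3.47 ± 0.24) fell, Tmem119 fell by 0.44 on the log2 scale, and Csf1r had a log2 fold change of 0.07 ± 0.12 (adjusted p = 0.607), but -0.28 (adjusted p = 0.00658) with library totals in place of TMM. MHC class II fell in 7 of 10 members and rose in 1, and border-associated macrophage genes fell in 8 of 12. The camera calls of these 2 lists (adjusted p = 0.0408 and 0.0331) were lost with an estimated correlation (adjusted p = 0.596 for each), with the replicate number as a block (adjusted p = 0.0647 and 0.0541) and without shielded library 2 without LPS (adjusted p = 0.0554 for each). That of MHC class II was also lost without shielded LPS library 3 (adjusted p = 0.148), and that of border-associated macrophages without shielded LPS library 1 (adjusted p = 0.05). Marrow-derived macrophage genes went both ways, with 9 rising and 10 falling of 28, a median of -0.17 and a camera test pointing up (adjusted p = 0.775). Apoe had a log2 fold change of -2.11 (-1.49 without shielded library 1 without LPS, -2.88 without the libraries with conflicting fields) and Ms4a7 one of -2.41. That of Ms4a7 was -3.33 without shielded LPS library 3, -1.80 without shielded library 1 without LPS and -3.17 without the libraries with conflicting fields. Clec12a was at -2.58, and at -3.41 without shielded LPS library 3. Disease-associated microglia genes also went both ways, 7 rising, such as Spp1 (4.37 ± 0.23), and 9 falling of 20, with a median of -0.05 and a camera test pointing up (adjusted p = 0.825). Lysosome and phagocytosis genes fell in 8 of 17 and rose in 3. Of the p53 and radiation list 10 of 19 rose and 3 fell, and of the cell cycle list 4 of 20 rose and 2 fell (median -0.06, camera pointing up, adjusted p = 0.825). Genes of the immediate-early and dissociation list, which handling of cells can raise, rose in 7 of 15 and fell in 1 (median 0.47, camera adjusted p = 0.282).

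Markers of other cells moved too. Monocyte genes rose in 6 of 11 and fell in 3, neutrophil genes rose in 2 of 12 (median -0.02, camera pointing up, adjusted p = 0.629), and B cell genes fell in 4 of 5. Endothelial genes fell in 5 of 9 and rose in 1, Cdh5 (1.03 ± 0.22), and astrocyte genes fell in 4 of 9 and rose in 2. Among these was Gfap (1.11 ± 0.39, edgeR adjusted p = 0.0246), whose call was lost without shielded LPS library 3 (adjusted p = 0.111) or shielded library 2 or 3 without LPS (0.0802 and 0.0637). All 8 oligodendrocyte genes and 8 of 9 neuronal genes fell, with medians of -1.43 and -1.55, and the mean neuronal level in the 3 shielded LPS libraries was 1.69, 2.67 and 3.99 log2 CPM. Adjusted over the list alone, the counts were 12 rising for MHC class I, 9 falling for neurons, 5 falling for B cells and 1 falling for the cell cycle, and those of the other lists were the same. In total 12738 of 18875 genes passed the edgeR threshold in shielded mice, 6119 higher and 6619 lower, and with a 2-fold minimum 2325 and 4670. Shielded LPS libraries had 15166 to 16569 genes with at least 10 counts, against 16985 to 18977 without LPS, and a mitochondrial share of 1.74 ± 0.201% against 2.17 ± 0.0135% of counts (SD, n = 3 each). With library totals in place of TMM the split was 4042 higher and 9131 lower, and the median of all genes moved from -0.14 to -0.49. The count was 8369 without the libraries with conflicting fields, 4524 higher and 3845 lower, where Sall1 (adjusted p = 0.103), Tmem119 (0.113) and Tlr4 (0.0935) did not pass. It was 6585 with the neuronal and oligodendrocyte level as a covariate, 3840 higher and 2745 lower, where Apoe (adjusted p = 0.0881), Clec12a (0.101), Ms4a7 (0.224) and Sall1 (0.0848) did not pass. Camera called 15 of the 27 lists, and none held with an estimated correlation (adjusted p = 0.49 to 0.618 for the called lists).

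**Figure D2:**
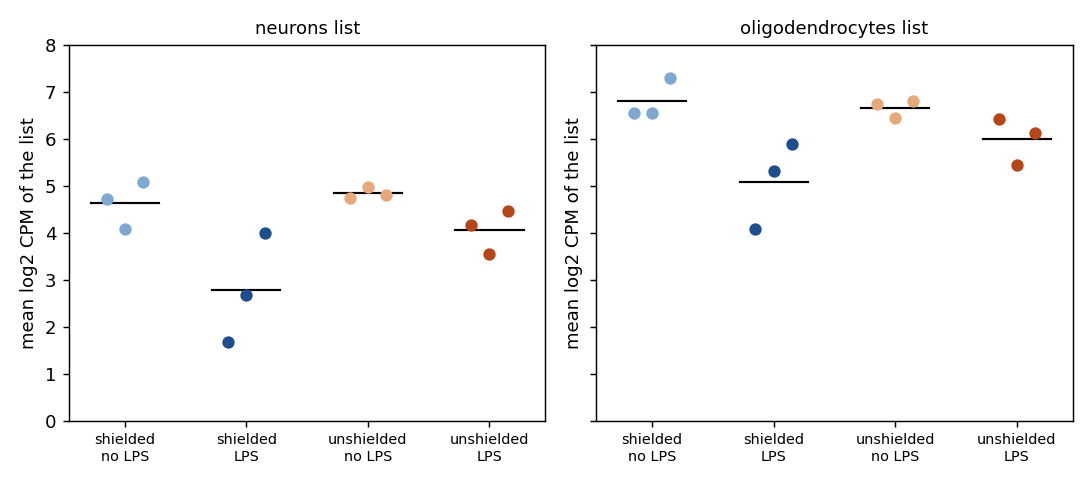
Mean log2 CPM of the neuron and oligodendrocyte lists (vertical axis) in each library, by group. Points are libraries in replicate order and lines are group means; the shielded LPS libraries span 1.69 to 3.99 for neurons and 4.08 to 5.88 for oligodendrocytes.

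The same question was then asked in unshielded mice. Jaml, an adhesion molecule of leukocytes, rose by 6.20 ± 0.71 and Saa3 by 6.19 ± 1.10 on the log2 scale. Ccl5 rose by 5.53 ± 0.53, Trem1, an activating receptor of myeloid cells, by 5.34 ± 0.41, Ifi205 by 5.32 ± 0.47, Steap4 by 4.99 ± 0.53, Il1rn by 4.95 ± 0.41, Lipg by 4.84 ± 0.47, the formyl peptide receptor Fpr2 by 4.82 ± 0.36 and Acod1 by 4.79 ± 0.51. Decreases were led by Cmah (-3.63 ± 0.33), Sncaip (-3.18 ± 0.19), Hpgd, a prostaglandin-degrading enzyme (-3.07 ± 0.27), Ighm (-3.04 ± 0.21) and the iron exporter Slc40a1 (-2.88 ± 0.29). EdgeR adjusted p-values of these genes were at most 0.00102. Without unshielded library 3 without LPS the log2 fold changes of the rising genes were larger: Saa3 9.79, Jaml 8.39, Ccl5 6.61, Steap4 6.50, Ifi205 6.25, Trem1 6.13, Acod1 5.74, Lipg 5.64, Fpr2 5.50 and Il1rn 5.38. Without unshielded library 1 without LPS Jaml was 5.62 and Saa3 5.58.

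Interferon-response genes rose in 29 of 30 members (median 2.04), NF-kB targets in 22 of 24 (1.95), acute-phase genes in 15 of 15 (3.71), cytokines and chemokines in 21 of 23 (1.93) and MHC class I in 13 of 13 (0.82). Isg15 rose by 3.42 ± 0.30, Cxcl10 by 2.79 ± 0.31, Gbp2 by 3.41 ± 0.31 and Lcn2 by 4.23 ± 0.72 (5.80 without unshielded library 3 without LPS). Among neutrophil genes 7 of 12 rose, with a median of 2.21, and among monocyte genes 7 of 11 rose and 2 fell. LPS receptor and adaptor genes rose in 10 of 15 and fell in 3, complement genes rose in 10 of 13 and fell in 1, and glycolysis genes rose in 11 of 15. Immediate-early and dissociation genes rose in 5 of 15 (median 0.49). The camera call of this list (adjusted p = 0.0377) was lost with an estimated correlation (adjusted p = 0.697) and without unshielded library 3 without LPS (adjusted p = 0.167) or unshielded LPS library 2 (0.118). MHC class II genes rose in 5 of 10 and fell in 2, and disease-associated microglia genes rose in 8 of 20 and fell in 5. Border-associated macrophage genes rose in 4 of 12 and fell in 4, and endothelial genes fell in 6 of 9 and rose in 1. Marrow-derived macrophage genes rose in 12 of 28 and fell in 5, with Ifitm2 (3.25 ± 0.14) and Cd38 (3.24 ± 0.19) among those that rose. Microglia identity genes fell in 16 of 29 and rose in 2, with Cx3cr1 at -1.98 ± 0.19, Mef2c at -1.16 ± 0.10 and P2ry12 at -1.21 ± 0.19. Tmem119 was 0.09 ± 0.12 (adjusted p = 0.575) and Apoe 0.34 ± 0.38 (adjusted p = 0.489). No neuronal gene and 1 of 8 oligodendrocyte genes passed the threshold, with medians of -0.81 and -0.66. Adjusted over the list alone, the counts were 4 rising for immediate-early genes, 18 falling for microglia identity, 7 falling for border-associated macrophages, 10 rising for neutrophils, 22 for cytokines, 11 for LPS receptor genes, and 12 for glycolysis, with 1 falling, and for complement. The edgeR test called 8128 genes, 4585 higher and 3543 lower, and with a 2-fold minimum 1339 and 1458. Unshielded LPS libraries had 18084 to 19224 genes with at least 10 counts, against 16375 to 18178 without LPS. Their totals were also larger, at 56776710 to 60495968 counts against 18090977 to 40792878. The number of genes reaching 10 counts depends on depth, so these ranges cannot show whether LPS changed it. The mitochondrial share was 1.91 ± 0.0855% in unshielded LPS libraries against 2.17 ± 0.0907% in unshielded libraries without LPS. With library totals the split was 2656 higher and 6520 lower, and the median of all genes moved from -0.06 to -0.36. Camera called 15 lists, none with an estimated correlation (adjusted p = 0.395 to 0.697). Il1b (0.82 ± 0.27, adjusted p = 0.0303) lost its call without unshielded LPS library 2 (adjusted p = 0.119) or unshielded library 2 or 3 without LPS (adjusted p = 0.0829 and 0.126), and with library totals (adjusted p = 0.0879). The monocyte list's call (camera adjusted p = 0.0337) was lost with an estimated correlation (adjusted p = 0.518) and without unshielded LPS library 2 (adjusted p = 0.0522).

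Across the 18875 genes the LPS fold changes in shielded and unshielded mice correlated at r = 0.831 (Spearman 0.835). Over all 36491 genes, without a low-count filter, r was 0.319, and with the conflicting libraries grouped by their treatment field it was 0.668; genes are not independent replicates, and no library was shared. Both effects called 4037 genes higher, against 1486 for independent lists, and 2905 lower, against 1242, while 91 were called in opposite directions, against 2756.

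**Figure D3:**
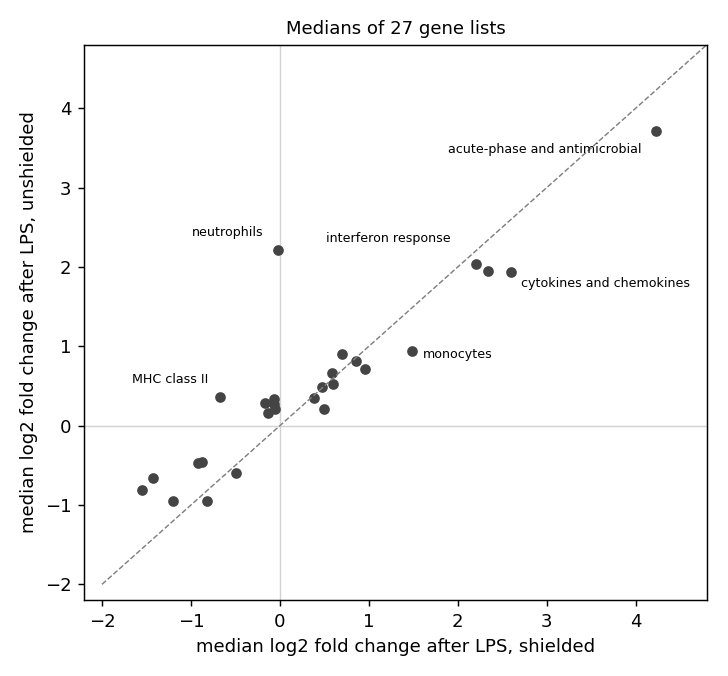
Median log2 fold change after LPS of each of the 27 gene lists in shielded (horizontal axis) and unshielded mice (vertical axis), with the line of equality dashed. The acute-phase list is at 4.22 and 3.71, the neutrophil list at -0.02 and 2.21, and the MHC class II list at -0.68 and 0.36.

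The next comparison asked how cells from unshielded mice differed from those of shielded mice without LPS. Of the marrow-derived macrophage genes 18 of 28 were higher, and of the microglia identity genes 20 of 29 were lower; camera with an estimated correlation called neither list (adjusted p = 0.474 for each). Gpnmb, a lysosomal glycoprotein, was higher by 3.50 ± 0.26, Gdf3 by 3.10 ± 0.49, Emilin1 by 2.77 ± 0.28, Ms4a14 by 2.69 ± 0.47, Klra2 by 2.61 ± 0.49, Ms4a7 by 2.56 ± 0.50, Dach1 by 2.56 ± 0.20, the RNA sensor Tlr8 by 2.51 ± 0.35, the scavenger receptor Msr1 by 2.46 ± 0.30 and Cmah by 2.44 ± 0.31. Apoe, a lipid carrier, took 8.13 ± 1.43% of counts in unshielded and 1.52 ± 0.939% in shielded libraries (SD, n = 3 each), a log2 difference of 2.39 ± 0.40. Its shares in shielded libraries 1 to 3 were 2.55, 0.7004 and 1.33%, and the log2 difference was 3.002 without shielded library 1 and 1.61 (adjusted p = 0.0456) without the libraries with conflicting fields. Without shielded library 1 Gdf3 was 3.71, Klra2 3.34 and Ms4a7 3.17, and without the libraries with conflicting fields Msr1 was 1.83. Lower genes included Klk8 (-2.47 ± 0.36), Liph (-2.39 ± 0.33), Ebf3 (-2.31 ± 0.34), Itgb3 (-2.28 ± 0.38), Gp9 (-2.28 ± 0.32), Plpp1 (-2.24 ± 0.28) and Sall1 (-2.23 ± 0.40). EdgeR adjusted p-values of these genes were at most 0.00713.

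Of 29 microglia identity genes 20 were lower and 1, Pmepa1, was higher (median -0.93), with Olfml3 at -1.26 ± 0.13, Tmem119 at -0.91 ± 0.12 and P2ry12 at -1.49 ± 0.19. Of 28 marrow-derived macrophage genes 18 were higher and 1, Clec4a3, was lower (median 0.99), with Pf4 at 1.64 ± 0.17, Mrc1 at 1.57 ± 0.17 and Clec12a at 2.14 ± 0.43. Border-associated macrophage genes were higher in 5 of 12. Disease-associated microglia genes were higher in 10 of 20 and lower in 4, with Spp1 at 1.99 ± 0.21, and this list's camera call (adjusted p = 0.0263) was lost with an estimated correlation (adjusted p = 0.686). It was also lost without the libraries with conflicting fields (adjusted p = 0.173), with the replicate number as a block (0.0533), and without shielded library 3 without LPS (0.129) or unshielded LPS library 2 (0.0918). MHC class II genes were higher in 6 of 10 and lower in 2. Complement genes were lower in 7 of 13 and higher in 1, neutrophil genes lower in 3 of 12, and lysosome genes lower in 5 of 17 and higher in 1, and interferon-response genes were higher in 3 of 30. The interferon call (camera adjusted p = 0.00622) was lost with an estimated correlation (adjusted p = 0.93), without the libraries with conflicting fields, where its direction reversed (adjusted p = 0.678), and without shielded or unshielded library 3 without LPS (adjusted p = 0.229 and 0.0697). The medians of the monocyte (-0.25) and cytokine lists (0.19) had the sign opposite to their camera tests (adjusted p = 0.772 and 0.99). Among the neuronal, oligodendrocyte, endothelial and immediate-early lists 0 genes passed the threshold, and 1 of 9 astrocyte genes was lower. The p53 and radiation list had 1 gene higher and 2 lower of 19. Adjusted over the list alone, the counts were 24 lower and 2 higher for microglia identity, 19 higher for marrow-derived macrophages, 11 higher and 5 lower for disease-associated microglia, 3 lower for MHC class II, 2 higher for complement, 7 lower for lysosome and 5 higher for interferon. Of the 10 genes read as a label check 0 passed the threshold, and Lcn2 was at 0.05 ± 0.65 (adjusted p = 0.985), against -1.56 (adjusted p = 0.037) without unshielded library 3. The edgeR test called 2043 genes, 751 higher and 1292 lower, and with a 2-fold minimum 325 and 338. Without the libraries with conflicting fields the count was 292, and 31 of 72 named genes kept their call; among those lost were Ms4a7 (1.80, adjusted p = 0.273), Clec12a (1.56, 0.308), Gdf3 (2.35, 0.114), Sall1 (adjusted p = 0.12), Klra2, Ms4a14, Tlr8, Itgb3 and Klk8. Without the libraries with conflicting fields, which leaves 1 library in the shielded group, Klra2 was 1.76, Ms4a14 1.96 and Tlr8 1.87. The folds of these 3 genes, like those of Ms4a7 and Gdf3, moved by over 1.5 times on the linear scale, and those of Sall1, Itgb3 and Klk8 did not. The count of genes called was 1139 without shielded library 2, and 1171 or 1094 without unshielded library 1 or 3. Camera called 10 lists, none with an estimated correlation (adjusted p = 0.474 to 0.93).

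**Figure D4:**
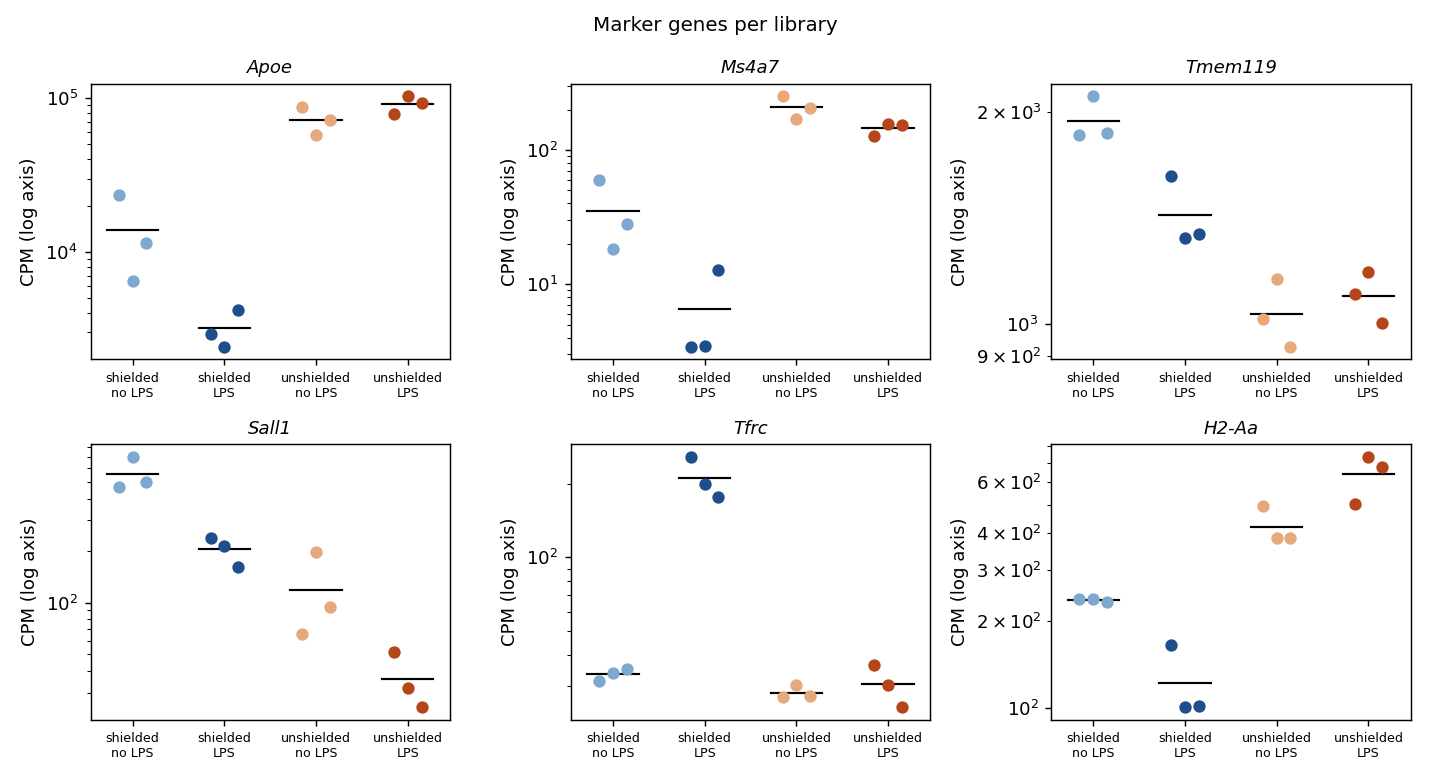
CPM on log axes of 6 genes in each library, by group; points are libraries in replicate order and lines are group means. Mean Apoe was 13820 and 3192 CPM in shielded mice without and with LPS and 72240 and 91410 CPM in unshielded mice, and mean Tfrc was 210.8 CPM in shielded LPS mice against 28.1 to 33.4 CPM in the other groups.

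The same comparison was made after LPS. In unshielded mice 18 of 28 marrow-derived macrophage genes, 8 of 12 border-associated macrophage genes and 8 of 10 MHC class II genes were higher, and 22 of 29 microglia identity genes were lower. Camera with an estimated correlation called none of these 4 lists (adjusted p = 0.707 for each). Gdf3 was higher in unshielded mice by 6.80 ± 0.72, Apoe by 4.84 ± 0.45, Ms4a7 by 4.46 ± 0.56, Tlr8 by 4.34 ± 0.38, Klra2 by 4.31 ± 0.54, the transcription factor Runx3 by 4.24 ± 0.32, Gpnmb by 4.24 ± 0.28, Emilin1 by 4.10 ± 0.30, Ms4a14 by 4.10 ± 0.56 and the receptor Flt3 by 4.07 ± 0.23. Lower in unshielded mice were Cxcl13 (-3.67 ± 0.53), Liph (-2.94 ± 0.33), Mrc2 (-2.89 ± 0.33), Postn (-2.86 ± 0.36), Il12b (-2.83 ± 0.50), Tfrc, the transferrin receptor (-2.79 ± 0.16), and Tnf (-2.07 ± 0.26). EdgeR adjusted p-values of these genes were at most 0.000999. Without shielded LPS library 3 Gdf3 was 9.72, Ms4a7 5.34 and Ms4a14 4.97, and without shielded LPS library 1 Gdf3 was 6.12, Cxcl13 -3.06 and Il12b -2.14. Saa3 (-0.04 ± 0.87, adjusted p = 0.976), Il1b (-0.43 ± 0.27, adjusted p = 0.204) and Il1rn (-0.25 ± 0.35, adjusted p = 0.561) did not pass.

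Microglia identity genes were lower in 22 of 29 and higher in 2 (median -0.87), with Cx3cr1 at -1.78 ± 0.19 and Sall1 at -2.50 ± 0.40. Marrow-derived macrophage genes were higher in 18 of 28 and lower in 1 (median 1.33), with Mrc1 at 3.48 ± 0.19 and Tgfbi at 3.10 ± 0.18. Border-associated macrophage genes were higher in 8 of 12. MHC class II genes were higher in 8 of 10 and lower in 1, H2-Oa, with H2-Aa at 2.38 ± 0.20 and H2-Eb1 at 2.35 ± 0.19. Cytokines and chemokines were lower in 11 of 23 and higher in 1, Il10, whose adjusted p without shielded LPS library 1 or 2 or unshielded LPS library 2 or 3 was 0.0858, 0.0932, 0.102 and 0.0585. Glycolysis genes were lower in 10 of 15 and higher in 2, and cholesterol synthesis genes in 9 of 16. NF-kB targets were lower in 7 of 24, LPS receptor and adaptor genes in 7 of 15 and complement genes in 6 of 13, with 1 complement gene higher. Immediate-early and dissociation genes were higher in 4 of 15 and lower in 1. Interferon-response genes were higher in 6 of 30 and lower in 3, disease-associated microglia genes were higher in 8 of 20 and lower in 6, and astrocyte genes were higher in 6 of 9 and lower in 1. The neuronal list had 1 of 9 members higher (median 0.94), and its camera call (adjusted p = 0.0365) was lost with an estimated correlation (adjusted p = 0.816) and without shielded LPS library 1 (adjusted p = 0.106) or unshielded LPS library 1 or 3 (adjusted p = 0.0529 and 0.0857). The calls of the cytokine and LPS receptor lists (camera adjusted p = 0.0228 and 0.0266) were lost with an estimated correlation (adjusted p = 0.816 for each) and without shielded or unshielded LPS library 1 (adjusted p = 0.0517 and 0.0529 for each list). Those of NF-kB targets and complement (camera adjusted p = 0.0365 for each) were lost with an estimated correlation (adjusted p = 0.831 and 0.707) and without the same libraries (adjusted p = 0.135 and 0.337 for NF-kB, 0.0586 and 0.05 for complement). That of glycolysis was lost with an estimated correlation (adjusted p = 0.816) and without shielded LPS library 1 (adjusted p = 0.0517). Adjusted over the list alone, the counts were 3 higher for microglia identity, 2 higher for cytokines, 11 lower for glycolysis, 6 lower for NF-kB targets, 0 lower for interferon, 9 higher and 7 lower for disease-associated microglia, 8 higher for astrocytes and 0 for neurons. The edgeR test called 8423 genes, 3596 higher and 4827 lower. With a 2-fold minimum the balance turned, to 2116 higher and 818 lower. Camera called 12 lists, none with an estimated correlation (adjusted p = 0.707 to 0.831). The shield differences with and without LPS correlated across genes at r = 0.545 (Spearman 0.506). Both called 583 genes higher, against 143 for independent lists, and 976 lower, against 330, with 48 in opposite directions, against 438.

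The last comparison tested whether the LPS effect itself differed by shield, as the effect in unshielded minus that in shielded mice. The effect was more positive in unshielded mice for Gdf3 (3.71 ± 0.93), Flt3 (2.88 ± 0.30), Pde7b (2.64 ± 0.45), Cd163, a haemoglobin scavenger receptor (2.46 ± 0.35), Apoe (2.45 ± 0.55), St6gal1 (2.42 ± 0.22), Runx2 (2.34 ± 0.40) and Runx3 (2.30 ± 0.41). It was more negative for Cxcl13 (-3.55 ± 0.86), Il12b (-3.51 ± 0.78), Ch25h, which makes an antiviral oxysterol (-2.83 ± 0.42), Tfrc (-2.54 ± 0.22), Gpr65 (-2.46 ± 0.30), Ikbke (-2.18 ± 0.45), Fn1 (-2.13 ± 0.29) and Ccl12 (-2.01 ± 0.32). EdgeR adjusted p-values of these genes were at most 0.0251. Cd163 went from 14.2 ± 1.39 to 60.4 ± 10.8 CPM in unshielded mice and from 7.82 ± 1.30 to 6.02 ± 2.47 CPM in shielded mice (SD, n = 3 each). Il12b reached 128.7 ± 88.2 CPM after LPS in shielded and 18.1 ± 8.91 CPM in unshielded mice.

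The difference of Gdf3 was 6.63 without shielded LPS library 3, 3.03 without shielded LPS library 1 and 3.06 without shielded library 1 without LPS. Without these last 2 libraries in turn that of Il12b was -2.82 and -4.18. That of Apoe was 1.80 without shielded library 1 without LPS and 3.22 without the libraries with conflicting fields, and that of Cxcl13 was -2.94 without shielded LPS library 1. MHC class II genes had a more positive effect in 5 of 10 members (H2-Eb1 1.57 ± 0.26, H2-Aa 1.55 ± 0.27), marrow-derived macrophage genes in 6 of 28, with 2 more negative, and border-associated macrophage genes in 4 of 12. Cytokines and chemokines had a more negative effect in 3 of 23, NF-kB targets in 1 of 24 (Tnfaip2, -1.37 ± 0.30) and LPS receptor and adaptor genes in 3 of 15, including Tlr2 (-1.74 ± 0.28). Over all 18875 tested genes 13.3% passed, 767 more positive and 1745 more negative in unshielded mice. Lysosome genes had a more positive effect in 3 of 17, and neutrophil genes in 0 of 12 (median 1.45). Microglia identity genes had a more positive effect in 3 of 29 and a more negative in 2, with a median of -0.02 and a camera test pointing up (adjusted p = 0.717), and disease-associated microglia genes in 3 and 3 of 20. Of the interferon list 0 of 30 and of the immediate-early list 0 of 15 passed, with medians of -0.24 and 0.17, and of the neuronal and oligodendrocyte lists 0 passed, with medians of 0.85 and 0.86. The medians of the endothelial (-0.14) and MHC class I lists (0.03) had the sign opposite to their camera tests (adjusted p = 0.72 and 0.818). Adjusted over the list alone, the counts were 6 more positive for MHC class II and for border-associated macrophages, 8 for marrow-derived macrophages, 5 for microglia identity and for lysosome, 4 for disease-associated microglia, and 6 more negative for NF-kB targets, with 1 more positive, and 4 for LPS receptor genes. The lysosome call (camera adjusted p = 0.0215) was lost with an estimated correlation (adjusted p = 0.882) and without shielded LPS library 3 (adjusted p = 0.293), shielded library 1 or 2 without LPS (0.0579 and 0.0621) or unshielded library 3 without LPS (0.131), and the NF-kB call with an estimated correlation (0.882) and without unshielded LPS library 1 (0.124). Tnf differed by -1.33 ± 0.36 (edgeR adjusted p = 0.0351). Its call held only when shielded LPS library 3, shielded library 2 without LPS, unshielded LPS library 2 or unshielded library 3 without LPS was left out, and its adjusted p was 0.0575 to 0.087 without any other library. The Gdf3 call was lost without shielded LPS library 1 or 2 (adjusted p = 0.069 and 0.0657), unshielded LPS library 3 (0.0579) or unshielded library 2 without LPS (0.054). The Cxcl13 call was lost without shielded library 2 or 3 without LPS (adjusted p = 0.0508 and 0.0527) or unshielded library 1 without LPS (adjusted p = 0.145, at a difference of -2.66).

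The edgeR test called 2512 genes, 767 more positive and 1745 more negative in unshielded mice. The balance turned with a 2-fold minimum, to 357 and 278, and without the libraries with conflicting fields, to 83 and 65, and without a low-count filter it was 750 and 821. Of the 4037 genes higher after LPS in both, 951 rose less and 49 more in unshielded mice, and of the 2905 lower in both, 258 fell less and 27 more. Without the libraries with conflicting fields the count was 148, and 20 of 57 named genes kept their call, among them Flt3, Pde7b, Cd163, Apoe, St6gal1, Runx2, Runx3, Tfrc, Gpr65 and Fn1, but not Gdf3 (4.44, adjusted p = 0.0528), Il12b (-2.81, 0.193), Cxcl13 (-3.19, 0.212), Ch25h (-2.48, 0.0735), Ikbke (-2.03, 0.167), Ccl12 (-1.71, 0.0766), H2-Aa (1.55, 0.0717), H2-Eb1 (1.53, 0.0612) or Tlr2 (-1.58, 0.0741). That fit has 1 library in the shielded group without LPS. Among these differences only those of Apoe, Gdf3 and Il12b moved by over 1.5 times on the linear scale. Without a low-count filter, where the count was 1571, Apoe (adjusted p = 0.0773), Il12b (0.0801) and Ikbke (0.0611) did not pass, and Apoe did not with the neuronal and oligodendrocyte covariate (0.0786). The count was 6391 without shielded LPS library 3, 2951 more positive and 3440 more negative, 1615 without shielded library 3 without LPS and 1635 without unshielded library 2 without LPS. Camera called 8 lists, none with an estimated correlation (adjusted p = 0.882). Fry's directional test called 2, of which 1, MHC class II (adjusted p = 0.0421), was among the 8.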

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

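The tests of mixing, of labels, of marrow-type genes and of RNA from other brain cells were chosen after the results were seen; those of GC content and of other splits were planned before. What drew attention below is a difference between shielded and unshielded mice in the effect of LPS, tested as an interaction in edgeR.

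The edgeR test called 2512 genes for a difference of LPS effects. Of 100 splits of the shield labels within each treatment, the real one included, 5 called at least as many, with 4654 the highest other. By the rule set beforehand chance was not excluded. Of the 99 other splits 8 called any gene, and these were the 8 that kept the LPS libraries of each kind together. Such splits keep the difference by shield after LPS. The share therefore depends on how many of them were drawn, and this test cannot decide on chance. For the other counts the 10 splits of 6 libraries are too few for a share under 0.05, with 1 split, the real one, calling 12738 genes for LPS in shielded mice, 8128 in unshielded mice, 2043 for the shield without LPS and 8423 after LPS; the highest other split called 0 in each, with 137 to 2914, 175 to 529, 129 to 1108 and 181 to 5784 genes at an unadjusted p under 0.05. In shielded mice the 4 splits that part all 3 same-numbered pairs gave 0 at most besides the real one.

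Differences of LPS effects in single genes (log2, unshielded minus shielded) were positive for Gdf3 3.71, Flt3 2.88, Pde7b 2.64, Cd163 2.46, Apoe 2.45, St6gal1 2.42, Ldhd 2.42, Runx2 2.34, Runx3 2.30, Stard13 2.15, Slco1a4 2.06, Mrc1 1.90, Trp53inp1 1.70, Tgfbi 1.64, H2-Eb1 1.57, H2-Aa 1.55, Igf1 1.46, Abcg1 1.22, Pltp 1.15, Gpr34 1.10, Mki67 1.07, Axl 0.97, Sox4 0.73, Hk1 0.73 and Lgmn 0.51. They were negative for Marco -4.64, Cxcl13 -3.55, Il12b -3.51, Ch25h -2.83, Tfrc -2.54, Gpr65 -2.46, Ikbke -2.18, Fn1 -2.13, Ccl12 -2.01, Msr1 -1.98, Dctd -1.98, C3ar1 -1.93, Tlr2 -1.74, Clec7a -1.42, Tnfaip2 -1.37, Tnf -1.33, Nuak1 -1.28, Irak3 -1.21, Slc1a3 -1.21, Cx3cr1 -1.20, Fas -1.15, Pilra -1.07, Ms4a6c -1.01, Aen -0.92, Ms4a6b -0.91, Slc2a1 -0.88, Tyms -0.81, Pcna -0.78, C4b -0.78, Ldha -0.62, Cyp51 -0.57 and Hmgcs1 -0.45. Over the 12 fits that leave out 1 library, calls were lost in 10 for Lgmn (edgeR adjusted p = 0.0557 to 0.0934), 9 for Gpr34 (0.062 to 0.0927), 8 for Mki67 (0.0508 to 0.094), Tnf (0.0575 to 0.087) and Ms4a6c (0.0509 to 0.0703), and 7 for C4b (0.0527 to 0.0638) and Tyms (0.0528 to 0.074). They were lost in 6 for Axl (adjusted p = 0.0615 to 0.0844), Sox4 (0.0609 to 0.0922) and Slc2a1 (0.0509 to 0.0562), 5 for Fas (0.0523 to 0.0609), and 4 for Gdf3 (0.054 to 0.069) and Igf1 (0.0518 to 0.0684). For Cxcl13 they were lost in 3 (adjusted p = 0.0508 to 0.145), and for Pilra and Ldha in 2 (0.0525 to 0.0534 and 0.0508 to 0.0516). Without the libraries with conflicting fields 20 of 57 named genes kept their call, and Marco was -8.91 and Apoe 3.22. Among those lost were Gdf3 (4.44, adjusted p = 0.0528), Msr1 (-1.36, 0.057) and Il12b (-2.81, 0.193). Without shielded library 1 without LPS Marco was -4.04, Il12b -4.18, Gdf3 3.06 and Apoe 1.80. Without shielded LPS library 1 Cxcl13 was -2.94, Il12b -2.82 and Gdf3 3.03, without shielded LPS library 3 Gdf3 was 6.63, and without unshielded library 1 without LPS Cxcl13 was -2.66. Among lists, camera gave adjusted p-values of 0.000929 for MHC class II, 0.00696 for marrow-derived and for border-associated macrophages, 0.0076 for cytokines and for NF-kB targets, 0.011 for neutrophils and for LPS receptor genes, and 0.0215 for lysosome genes; with an estimated correlation each was at an adjusted p of 0.882, and fry's directional test called 1 of these 8, MHC class II (adjusted p = 0.0421).

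Genes higher by 4-fold or more in unshielded mice without LPS, 72 in number, had a median LPS effect of -1.02 in shielded and -0.16 in unshielded mice. Whether LPS lowers these genes by about as much in both kinds of mice cannot be told apart from an unequal effect: the median difference was 0.711, with a 95% interval over libraries from -0.142 to 1.57 for the set's median, and the set was chosen on the libraries without LPS that enter both effects, which pushes the difference down. A varying share of marrow-derived or border macrophages among shielded libraries may contribute, since the set was higher in shielded library 1 than in library 2, both without LPS, by a median of 0.937, with 94.4% of genes in that direction. That pair was the widest, with medians of 0.654 for library 1 against 3 and -0.34 for 2 against 3. The 9 border genes in neither the set nor the marrow-derived list differed between libraries 1 and 2 by a median of -0.22. Libraries 2 and 3 are also those whose treatment field says LPS. Cells of different make-up and a different response of the same cells both stay open.

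Neuronal and oligodendrocyte genes were lower in shielded LPS libraries. A varying amount of RNA from other brain cells among libraries may account for part of this: over the 12 libraries, deviations of the neuronal list from the group means followed those of the oligodendrocyte (r = 0.874, exact permutation p = 0.044; rho = 0.72, p = 0.0718) and astrocyte lists (r = 0.908, exact permutation p = 0.0162; rho = 0.783, p = 0.0201), with adjusted p = 0.088 and 0.0648 over 4 relations. The relation with endothelial genes had r = 0.501 (exact permutation p = 0.209) and that with microglia identity genes r = -0.154 (exact permutation p = 0.458), and without shielded LPS libraries 1 and 3, the 2 farthest, r was 0.656 for oligodendrocytes and 0.696 for astrocytes. GC content and transcript length account for little, since the median of the 17 genes was -1.55 before and -1.40 (-1.399) after removing their trend. An effect of LPS on these cells or their recovery stays untested.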

How the results depend on the processing

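Of the named genes' values under all alternatives, 10660 kept their side of the threshold and, where called, their direction. A call was lost by 941 and gained by 89, and 16 reversed with a call in either fit. Values called in neither fit count as kept whatever their direction. Grouping by the treatment field, which the label check argues against, gave 379 of the lost calls and 13 of the reversals. For lists these were 2302, 136, 114 and 13, and fry's mixed test could not count as reversed. The cause of each change was not tested unless stated. A 2-fold minimum left 6995 genes for LPS in shielded mice, 2797 in unshielded mice, 663 and 2934 for the shield without and after LPS, and 635 for the difference, fewer by construction. Without a low-count filter the difference had 1571 genes and the LPS effects correlated at 0.319. Without the libraries with conflicting fields, and so with 1 library in that group, which is assumed to vary like the others, LPS in shielded mice had 8369 genes, the shield without LPS 292 and the difference 148. Grouped by the treatment field, edgeR called 0, 117, 0, 1464 and 0 genes in the order above, and the LPS effects correlated at 0.668. For the 3 counts of 0, 284, 809 and 481 genes had an unadjusted p under 0.05, limma-voom called 0 in each and DESeq2 1, 111 and 24. The neuronal and oligodendrocyte covariate, chosen after seeing the data, gave 6585 genes for LPS in shielded mice and 3426 for the shield without LPS.

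Leaving out each library gave 1094 to 2353 genes for the shield without LPS, 1615 to 6391 for the difference, and correlations of 0.76 (without shielded LPS library 3) to 0.838. The list tests had 60 calls, 0 with an estimated correlation, 61 with fry's directional test, of which 48 were shared, and 109 with fry's mixed test. For the difference camera called 8 lists and directional fry 2. With the replicate number as a block the counts were 13172, 8829, 2355, 9408 and 2891, and 11809 in the shielded groups alone, a fit added after seeing the data; none moved by over 1.5 times. The block changed the calls of few named genes: in LPS in shielded mice all 114 kept their call, 105 of 105 in unshielded mice, 72 of 72 and 96 of 97 by shield without and after LPS, and 55 of 57 in the difference; in the shielded groups alone 110 of 114 did.

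With library totals Ctss was -0.066 and Csf1r -0.28 after LPS in shielded mice. Grouped by the treatment field, the direction reversed for Cd4 (0.004) and Fdps (0.046) after LPS in shielded mice; for Sox4 (-0.25), Slco1a4 (-1.07), Itm2a (-0.72), Trim30a (0.15), Psme2 (0.006) and Gas6 (-0.29) by shield after LPS; and for Sox4 (-0.37), Gpr34 (-1.38), Ms4a6c (0.088), Slco1a4 (-1.72) and Pltp (-0.12) in the difference. Lcn2 by shield without LPS ran from -1.56 without unshielded library 3 to 0.547 without shielded library 1, both without LPS. Lists that reversed had these camera adjusted p-values: interferon, shield without LPS, 0.678 without the conflicting libraries and 0.862 by the field; and by the field, marrow-derived macrophages after LPS in shielded mice 0.0163; cytokines 0.504, NF-kB 0.142 and acute-phase 0.0345 by shield after LPS; and in the difference microglia 0.0072, endothelial 0.00205, cytokines 0.0642, interferon 2.99e-07, NF-kB 0.0361, acute-phase 0.00206 and MHC class I 0.00205.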

Other observations

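A set of 16 iron and metal genes was examined after the values had been seen, and no explanation was tested. The difference of LPS effects passed for 4 of them, each more negative in unshielded mice, and not for the other 12. LPS called 15 of the 16 in shielded and 11 in unshielded mice. Over all tested genes the difference passed for 13.3%, with 1745 of 2512 more negative, and LPS called 67.5% in shielded and 43.1% in unshielded mice. The transferrin receptor gene Tfrc rose after LPS by 2.66 ± 0.16 in shielded mice (edgeR adjusted p = 6.34e-08) and was 0.11 ± 0.15 in unshielded mice (adjusted p = 0.557), and the difference passed (-2.54 ± 0.22, adjusted p = 0.000464). Ireb2 and Aco1, which encode iron regulatory proteins, rose in shielded mice by 0.56 ± 0.09 and 0.70 ± 0.08, with differences of -0.42 ± 0.12 and -0.52 ± 0.12 (edgeR adjusted p = 0.0381 and 0.0138), and Steap3, a ferrireductase, had a difference of -0.91 ± 0.23 (adjusted p = 0.0201). Whether the calls of Ireb2, Aco1 and Steap3 hold under the alternatives or with a library left out was not examined. The iron exporter Slc40a1 fell in both, by 2.77 and 2.88 on the log2 scale, and the ferritin gene Fth1 rose in both, by 1.83 ± 0.17 and 1.55 ± 0.16. The metallothionein genes Mt1 and Mt2 rose by 3.26 ± 0.22 and 4.98 ± 0.58 in shielded and by 3.39 ± 0.22 and 4.43 ± 0.56 in unshielded mice. Hmox1 rose by 1.19 ± 0.20 and 1.18 ± 0.20.

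Unshielded library 3 without LPS held more RNA of many strongly LPS-induced genes than its companions, and the tests here were chosen after this was seen. Not every LPS-response gene was higher. Il1b was at 136.8 CPM against 222.6 and 179.9 in libraries 1 and 2, and Tnf at 35.59 against 52.15 and 43.82. Cxcl10 was at 24.93 CPM against 28.44 and 19.6, and the NF-kB list at a mean log2 CPM of 5.386 against 5.503 and 5.367. A label swap is argued against by its label-check mean, 2.828 below the lowest LPS library. A small share of RNA from unshielded LPS libraries may have been mixed in. Genes were taken that were induced at least 16-fold in shielded mice and reached 20 CPM in unshielded LPS libraries. The fold used shielded libraries only. The genes also had to pass the edgeR threshold for LPS in shielded mice, and that fit and its scaling included all 12 libraries. In library 3, 38 of 38 such genes lay above the mean of libraries 1 and 2, and at 8-fold 91 of 103. The median implied shares were 3.63% and 3.39%. Over 37 genes induced at least 16-fold above libraries 1 and 2, a choice that itself favours library 3 lying above them, the ratio of the 75th to the 25th percentile of the implied shares was 1.86, but the cutoffs for induction had not been set in advance, and over 9 pairs of cutoffs the ratio ran from 1.67 to 2.52, with 6 at or under 2. Simulated mixing gave 1.22 to 1.34, but it added counting error only and took the mean of libraries 1 and 2 as free of error. Its range is therefore too narrow to set against these ratios. Mixing and an animal with a mild immune response of its own cannot be told apart.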
